A study of Saccharomyces cerevisiae with 11 samples.

How the data were processed

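Ribosome profiling measures translation from the RNA fragments that ribosomes protect. In this series SK1 yeast cells were treated with lactimidomycin before lysis, so that footprints gather at start codons. Per the labels' protocols, frozen cells were milled in lysis buffer and the extract was clarified before footprints were prepared. Per the submitters' processing notes, CASAVA, bcl2fastq 2.17 and Bowtie2 were used. Their settings, any removal of ribosomal RNA, the trimming and the assignment of reads to positions are not given in the sources used here.

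The rating table gives 1 value per candidate ORF and none for single libraries. Per the notes deposited with it, the authors fitted regressions to the LTM footprints and to a data set named CHX, which is not described further, and a random forest trained on annotated and other coding sequences turned 6 regression features into a score from 0 to 1 per ORF. The start codon is not among those features. The deposited rating is a second score, the forest score adjusted for overfitting, given where the forest score is above 0.5. The W statistics deposited for start codons are also a score, called LTM evidence here, with no stated scaling to depth or length. The deposited ratio of each ORF to the strongest ORF with the same stop codon was read but decided no result. Column names carry the ending nosat, which the notes do not explain, so which libraries entered the values is uncertain. Of columns for single libraries there are 0 here, so the planned comparison of conditions was not run and the depth per library is unknown.

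The table holds 192230 candidates of 17 classes. The classes of upstream, start-overlapping and stop-overlapping ORFs are named but not described in the notes, and 99.6% of upstream ORFs were checked to end before the annotated start. Coordinates are those of the deposited SK1 annotation, given here counted from 1, from the first base of the start codon to the last base of the stop codon. The start of annotated ORFs matched that annotation in 2392 of 2420 genes on the plus strand and 2364 of 2384 on the minus strand. Gene symbols were taken from the S288C reference (R64) by locus tag. SK1 coordinates were never placed on S288C. For sequence context, a start was located in S288C by its distance from the annotated start of the same gene and kept where the codon and reading frame were the same there, which held for 91.0% of candidate extensions and 72.3% of candidate upstream ORFs. The genome sequence of SK1 was not used here.

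An ORF was called rated at a forest score above 0.5. The design, fixed before the data were examined, took the cut-off from the deposited notes. These state 2, above 0.5 and above 0.1, and the higher was chosen after the table had been opened and after counts per class and codon had been seen at several cut-offs. The score has different baselines by class, so that 0.1 is passed by nearly every upstream ORF, and the notes state that no single value serves all classes. Cut-offs of 0.9 (planned) and of 0.1 and 0.8 (added) were run for all classes, and a cut-off of 0.5, which had been listed as an alternative, is the one used. Shares have exact (Clopper-Pearson) 95% intervals. Codons, classes and gene lists were compared with two-sided Fisher's exact tests, odds ratios with normal-approximation 95% intervals on the log scale, and Benjamini-Hochberg adjustment over 9 codons or 13 lists at a false discovery rate of 0.05. Where a cell of a table was 0, 0.5 was added to each cell for the odds ratio, and the direction of a result was read from the shares, a choice made after other cut-offs had been seen. Medians were compared by 100000 permutations. Background were the candidates of the same class, and for lists the genes with a candidate and an annotated ORF in the table. The 13 gene lists were written from general knowledge before the data were examined. 37 names of early meiosis stood for 35 genes and 49 of mid and late sporulation for 48.

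Named genes were chosen by a rule fixed before the data were examined: ALA1, GRS1 and every aminoacyl-tRNA synthetase or gene with a known alternative start that had a rated extension or truncation; the 10 near-cognate extensions with the highest rating; the 5 highest-rated AUG extensions, AUG upstream ORFs, near-cognate upstream ORFs and ORFs outside annotated genes; up to 10 known upstream ORF genes; and the 3 longest near-cognate extensions. Highest rating means the deposited rating, while the text prints forest scores. For ORFs outside annotated genes, the class of ORFs on transcripts without an annotated coding sequence in the table was used. ORFs of that class can begin at a gene's own annotated start. A gene that the rule selects is not reported here. Members named beside list counts, and genes named for ratios against the annotated start, are exceptions chosen after their values were seen. The start-overlapping class, extensions of at least 4 codons, near-cognate starts alone and AUG starts alone for length, and the comparison of AUG with near-cognate starts in further classes were added after the table had been seen.

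The codon, list and length tests were tested on simulated data before use, and the test of sequence context after its first use. With 23191 upstream candidates, changes of the odds by 3, 2 and 0.4 times were found in 100% of 100 draws, and in 9% of draws without any effect at least 1 codon was called. With 2666 extension candidates these were found in 97%, 25% and 79%, and 3% of draws without an effect gave a call. The draws took ORFs as independent, while ORFs on a shared transcript are not, so these rates need not hold for the data. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used. Left out of the comparisons were smaller classes, of which ORFs downstream of genes and over stop codons are given in the closing part.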

Results

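The deposited data describe where ribosomes start translation in budding yeast (Saccharomyces cerevisiae) of the SK1 strain, a background that sporulates efficiently. Cells were treated before harvest with 3 µM lactimidomycin (LTM), a drug that holds ribosomes at start codons, and the ribosome-protected RNA fragments were sequenced. There were 11 libraries, each the only one of its group. The vegetative libraries came from exponential (OD600 0.6) and saturated (OD600 10) cultures. The sporulation libraries were taken 0, 1.5, 3, 4.5, 6, 8, 10 and 22 h after transfer to sporulation medium, with a MATa/a library at 4.5 h, a mating-type state in which cells cannot enter meiosis. The measurement analysed here is 1 table in which each candidate open reading frame (ORF) has a single score from 0 to 1. Shares below are of these candidates and not of all possible starts. The table has no columns for single libraries, and which libraries entered it is uncertain. Neither a depth per library nor a comparison between vegetative and meiotic cells can therefore be given. No value has a replicate. Intervals and p-values below treat ORFs as the unit within this table, and ORFs that share a transcript are not independent.

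The table held 192230 candidate ORFs that begin with AUG or with 1 of the 9 codons that differ from AUG in a single base (near-cognate codons). A score above 0.5 was reached by 25868 of them, and these are called rated ORFs. The share of annotated protein-coding ORFs that were rated is given first. Annotated coding sequences were part of the training set of the score, so this share is not an independent control. Of 4814 annotated ORFs in the table, 4492 were rated (93.3%, exact 95% interval 92.6 to 94.0). The deposited annotation holds 6707 genes, of which 4804 had an annotated ORF in the table and 4488 a rated one. The shares here are therefore of ORFs in the table and not of the whole annotation. Among ORFs classified as verified, 3751 of 3984 were rated (94.2%), and among uncharacterized ORFs 688 of 752 (91.5%). ORFs classified as dubious, which are thought unlikely to encode a protein, were rated less often, in 51 of 76 cases (67.1%, exact 95% interval 55.4 to 77.5). The odds of a rating were 7.89 times higher for verified than for dubious ORFs (95% interval 4.80 to 13.0, p = 1.63e-12, two-sided Fisher's exact test).

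The first question, which the title of the series names, was how often translation starts at codons other than AUG, in particular to make longer forms of known proteins. N-terminal extensions are ORFs that start upstream of the annotated start in the same frame and end at the same stop codon. Of 2666 candidate extensions with a near-cognate start, 97 were rated (3.64%), in 93 genes. Of 69 candidate extensions with an upstream AUG, 28 were rated (40.6%). The odds of a rating were 18.1 times higher for AUG (95% interval 10.7 to 30.5, p = 5.14e-21, Fisher's exact test). Near-cognate codons nevertheless made up 77.6% of rated extensions, because their candidates were far more numerous. The exact test of AUG against near-cognate extensions did not pass at a score above 0.9 (odds ratio 13.1, exact p = 0.0972). At a score above 0.1, the lower cut-off of the deposited notes, 596 near-cognate extensions in 482 genes passed, and at a score above 0.9 only 3 did.

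Genes known to make an alternative N-terminus were found among these. ALA1, the single alanyl-tRNA synthetase gene that serves both cytosol and mitochondria, had an ACG extension of 25 codons with a score of 0.776. It starts at position 959114 of SK1 chromosome 15 (minus strand) and its ORF ends at 956163. In the S288C reference (R64) the matching ACG lies at 949184 of chromosome XV, within ATTTAAGACAAGACGACGTCAACTACC, in which the codon follows the first 12 bases. The LTM evidence at the ACG was 0.198 times that at the annotated AUG. HFA1, the mitochondrial acetyl-CoA carboxylase, had an AUU extension of 124 codons with a score of 0.888, starting 372 nucleotides upstream of the annotated AUG at 673342 of SK1 chromosome 13, and an AUA extension of 127 codons with a score of 0.739. KGD4, a subunit of the mitochondrial 2-oxoglutarate dehydrogenase complex, had the highest-rated near-cognate extension, a UUG start 30 codons upstream at 251539 of chromosome 6 with a score of 0.960. GRS1, the glycyl-tRNA synthetase gene with a known UUG start, had a single candidate extension among the rows analysed here, an AUC with a score of 0.0175, so its UUG start is not analysed here.

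CLB1, a B-type cyclin of meiosis and mitosis, had an AUA start 17 codons upstream (710745 of chromosome 7, score 0.952), with 2.83 times the LTM evidence of its annotated AUG. NAB6, an RNA-binding protein, had a UUG extension of 21 codons (score 0.868), and RNR3, a subunit of ribonucleotide reductase, a UUG extension of 36 codons (score 0.863). The CUG extension of SYT1, 25 codons long with a score of 0.867, had 10.7 times the evidence of the annotated start, and that of RIE1, 29 codons long with a score of 0.875, had 5.67 times. UUG extensions were also rated in YDR541C (16 codons, score 0.825) and TOS3 (17 codons, score 0.859), the latter a kinase that acts on Snf1. DAL5, the allantoate permease, had an AAG extension of a single codon with a score of 0.909. After the pair in HFA1, the longest rated near-cognate extension was that of APP1, 70 codons from an AAG (score 0.628).

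Among AUG extensions, the highest by the deposited rating, here with their forest scores, were in SEN34, a subunit of the tRNA splicing endonuclease (25 codons, score 0.903), LIH1 (15 codons, score 0.871), RSM18, a mitochondrial ribosomal protein (15 codons, score 0.886), STE11, a kinase of the pheromone pathway (10 codons, score 0.868), and DCS2 (1 codon, score 0.866). SUC2, the invertase, had an AUG extension of 1 codon (score 0.754) and MSF1, the mitochondrial phenylalanyl-tRNA synthetase, an AUG extension of 5 codons (score 0.751). The annotated start of MSF1 was itself below the cut-off, at 0.171, as was that of LIH1, at 0.143.

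The LTM evidence of an extension was compared with that of the annotated start where both were in the table. For 80 near-cognate extensions the median ratio was 0.122 (interquartile range 0.0501 to 0.403), and 15 of the 80 exceeded the annotated start. For 19 AUG extensions the median ratio was 1.13, and 10 exceeded it. LTM evidence enters the score, so these ratios describe rated extensions only.

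**Figure D1:**
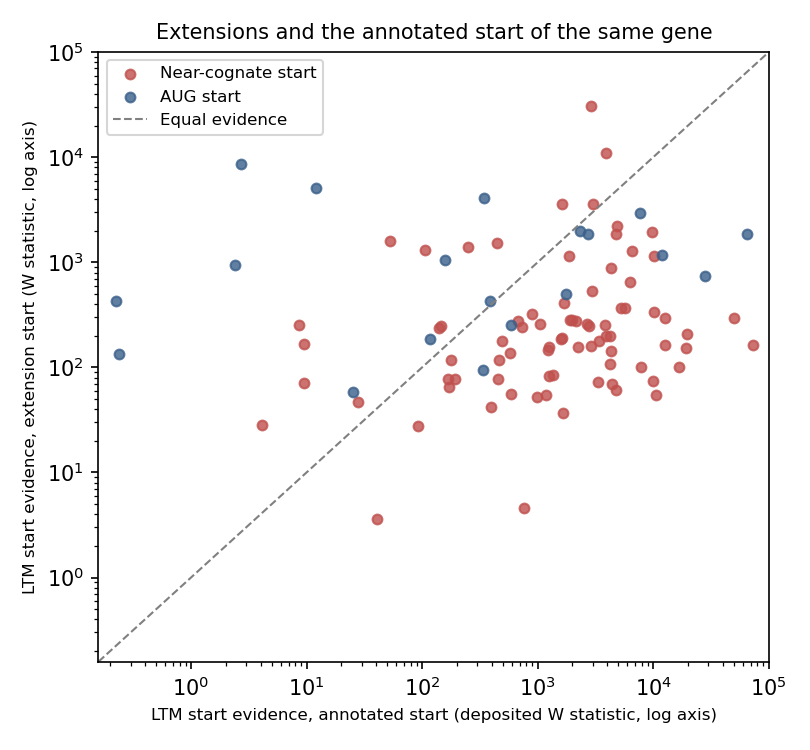
LTM start evidence (the deposited W statistic, log axes) of rated extensions, vertical, against the annotated start of the same gene, horizontal. Each point is 1 extension, and the dashed line marks equal evidence. Shown are 80 of 97 rated extensions with a near-cognate and 19 of 28 with an AUG start. The others have no annotated start in the table. Near-cognate extensions lie mostly below the line, with a median ratio of 0.122.

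Rated near-cognate extensions added more codons than unrated ones, with a median of 16 codons for 97 rated and 6.5 for 2528 unrated extensions (difference 9.5, permutation p = 1e-05). For AUG extensions the medians were in the other order, 9 codons for 28 rated and 17 for 39 unrated (difference -8, permutation p = 0.163). The share of AUG candidates that were rated went from 3 of 3 at 1 codon, 5 of 7 at 2 to 3 codons and 6 of 16 at 4 to 9 codons to 4 of 13 at 40 or more. Over both kinds of start the median was 15 codons (interquartile range 4 to 22) for 125 rated and 7 codons (3 to 14) for 2567 unrated extensions, a difference of 8 codons (permutation p = 1e-05, the smallest that 100000 permutations can give). The share of near-cognate candidates that were rated did not rise steadily with length. It was 6.16% for an extension of 1 codon (18 of 292), 0.926% for 2 to 3 codons (5 of 540), 1.15% for 4 to 9 codons (9 of 786), 5.60% for 10 to 19 codons (33 of 589), 8.06% for 20 to 39 codons (27 of 335) and 6.02% for 40 or more (5 of 83). FRS2, the phenylalanyl-tRNA synthetase alpha subunit (AAG, score 0.692), and MSY1, the mitochondrial tyrosyl-tRNA synthetase (AUC, score 0.813), were among the extensions of 1 codon. At a score above 0.1 the medians did not differ (difference 0, permutation p = 1).

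**Figure D2:**
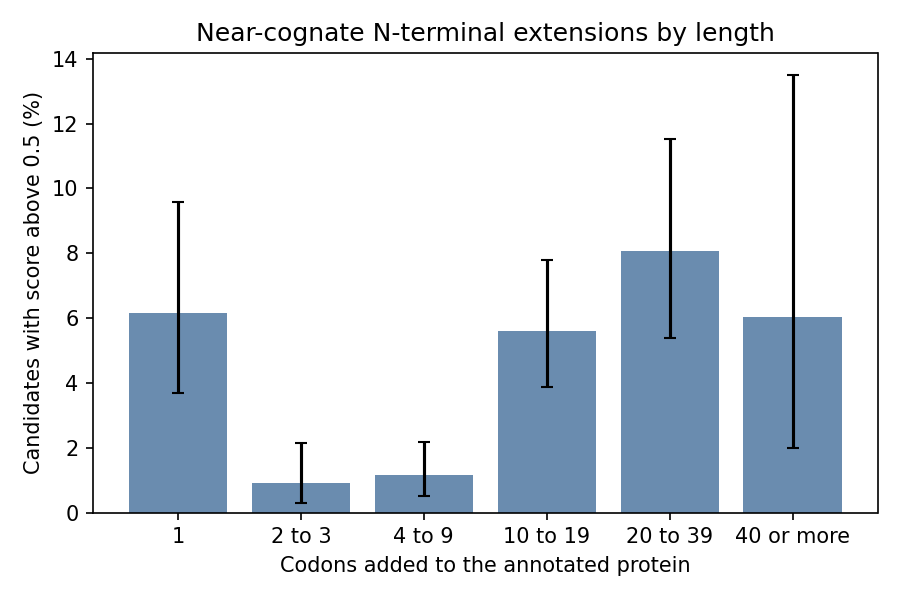
Share of candidate near-cognate extensions with a score above 0.5 (vertical, percent) by the number of codons they add (horizontal); bars start at 0 and error bars are exact 95% intervals. Extensions of 1 codon (6.16%) and of 10 or more codons stand above those of 2 to 9 codons.

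Start codons were compared within each kind of ORF, each codon against the other 8 near-cognate codons. In extensions UUG was rated most often, in 29 candidates (10.1% of those with this codon, exact 95% interval 6.85 to 14.1), with an odds ratio of 3.80 against the other codons (adjusted p = 1.08e-06, Fisher's exact test with Benjamini-Hochberg adjustment over 9 codons). AAG was rated least often, in 5 of 454 (1.10%, odds ratio 0.257, adjusted p = 0.00354 by the same exact test). The other 7 codons did not pass: GUG (8.00%) and AUA (2.04%) both had an adjusted exact p of 0.051, and CUG (5.59%), AUU (3.55%), AGG (3.38%), ACG (3.06%) and AUC (2.33%) had adjusted exact p of 0.377 or higher. In tables simulated with 2666 candidates, a codon with 3 times the odds was found in 97% of draws, AAG with 0.4 times the odds in 79% and CUG with 2 times the odds in 25%. With each gene counted once GUG (odds ratio 2.56, adjusted exact p = 0.0274) and AUA (odds ratio 0.387, adjusted exact p = 0.0163) passed as well, and GUG in genes with a rated annotated ORF (odds ratio 2.72, adjusted exact p = 0.0475). Above 0.1 CUG, GUG, AUA and AGG passed the exact test. UUG and AAG did not pass above 0.8 (UUG odds ratio 3.92, adjusted exact p = 0.0585; AAG 0.230, adjusted exact p = 0.350) or above 0.9, and AAG did not pass above 0.1 (odds ratio 0.875, adjusted exact p = 0.322).

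Upstream ORFs, which start before the annotated AUG and in 99.6% of cases also end before it, showed the same extremes with far more candidates. Of 31402 candidates, 6915 were rated (22.0%), in 2770 genes, with a median of 2 per gene and up to 16 in ACC1. UUG led with 33.1% of 4952 candidates (odds ratio 2.65, 95% interval 2.47 to 2.85, adjusted exact p = 1.07e-149), followed by CUG with 26.2% (odds ratio 1.53, adjusted exact p = 4.53e-14). GUG (20.6%) and ACG (19.3%) did not differ from the rest by the exact test. AUU (16.7%), AUA (16.7%) and AUC (10.8%) were rated less often, and AGG (4.44%) and AAG (4.07%) least, AAG with an odds ratio of 0.161 (adjusted exact p = 1.57e-96). AUG starts were rated in 2409 of 8211 cases (29.3%), against 4506 of 23191 near-cognate starts (19.4%, odds ratio 1.72, p = 3.05e-74, Fisher's exact test). UUG upstream ORFs were thus rated at a share above that of AUG, 33.1% against 29.3%, a pair that was not tested.

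Near-cognate starts made up a larger part of rated extensions (77.6%) than of rated upstream ORFs (65.2%), with an odds ratio of 1.85 (95% interval 1.21 to 2.83, p = 0.00321, two-sided Fisher's exact test). The candidates differed in the same direction, with near-cognate starts in 97.5% of candidate extensions and 73.9% of candidate upstream ORFs. The test used rated ORFs alone, so it does not show that near-cognate extensions were rated more readily. Relative to their candidates, near-cognate starts were rated less often than AUG in both classes. The odds ratio of a rating for AUG was 18.1 in extensions and 1.72 in upstream ORFs, values that were not tested against each other. The difference in rated ORFs had an odds ratio of 2.94 with each gene counted once (exact p = 1.71e-07) and 5.28 above 0.1 (exact p = 1.17e-38). Above 0.1, 30642 of 31402 upstream candidates passed, so there the upstream side is nearly that of the candidates. It was not found at a score above 0.8 (odds ratio 1.08, exact p = 0.86) or above 0.9 (odds ratio 2.03, exact p = 0.652, from 4 rated extensions).

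ORFs that overlap the annotated start in another frame, a class compared only after the table had been seen, ranked codons much like upstream ORFs. UUG was rated in 35.8% of 877 candidates and AAG in 4.76% of 798 (odds ratios 3.66 and 0.216, adjusted exact p = 9.74e-51 and 1.42e-27). Inside coding regions the picture differed. Among 81932 out-of-frame near-cognate candidates the highest share belonged to AUA (10.4%), then AUC (9.48%), while UUG had 6.89%, below the other codons (odds ratio 0.911, adjusted exact p = 0.0392), and AAG 4.28%. That low position of UUG turned to odds ratios of 1.33 above 0.8, 1.36 above 0.9 and 1.15 with each gene counted once, none of which passed the exact test. The highest share was 2.44 times the lowest there, against 9.14 times in extensions, 8.12 times in upstream ORFs and 4.81 times in truncations. In truncations, which start inside a coding region in its own frame, UUG (2.47%) and CUG (2.37%) were rated most often and AGG (0.513%) least. The deposited notes warn that calls inside coding regions have a very high rate of false positives, from ribosomes that were elongating.

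**Figure D3:**
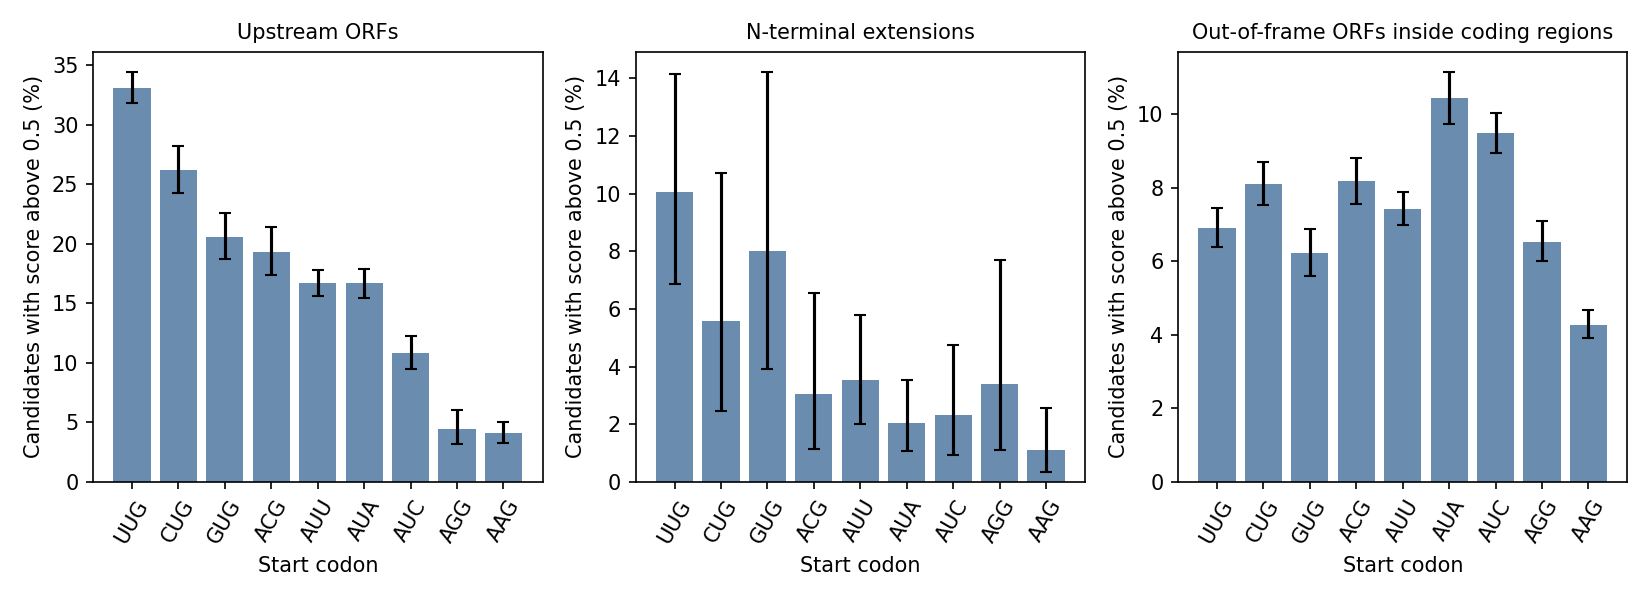
Share of near-cognate candidates with a score above 0.5 (vertical, percent, a separate scale per panel) for each start codon (horizontal) in upstream ORFs, N-terminal extensions and out-of-frame ORFs inside coding regions; bars start at 0 and error bars are exact 95% intervals. UUG is highest in upstream ORFs (33.1%) and extensions (10.1%) but not inside coding regions (6.89%).

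Truncations that start at an AUG were rated in 461 of 4466 cases (10.3%). They included aminoacyl-tRNA synthetases and genes listed beforehand for a known alternative start. For several of these, a mitochondrial form is made from the first AUG and a form outside mitochondria from a later AUG. Whether each AUG below is such a known start was not checked. HTS1, the histidyl-tRNA synthetase, had its AUG 20 codons downstream rated at 0.923. TRM1, a tRNA methyltransferase, had an AUG 16 codons downstream at 0.869, CCA1, the tRNA nucleotidyltransferase, an AUG 9 codons downstream at 0.861, and GLR1, the glutathione reductase, an AUG 16 codons downstream at 0.866. VAS1, the valyl-tRNA synthetase, had an AUG 46 codons downstream at 0.618. MOD5, a tRNA isopentenyltransferase, had AUG truncations 11 and 223 codons downstream at 0.616 and 0.801, and TRZ1, the tRNase Z, had an AUG 71 codons downstream at 0.550. In CCA1 the downstream AUG had 34.3 times the LTM evidence of the first AUG, in GLR1 4.39 times and in TRZ1 0.0302 times. The AUG codons of MOD5 11 and 223 codons downstream had 0.149 and 0.767 times that of its first AUG. HTS1, TRM1 and VAS1 had no annotated ORF in the table, so their later AUG could not be compared with the first. MSE1 had an AUG and a UUG truncation, 2 and 3 codons downstream (scores 0.609 and 0.573), and single-codon truncations were rated in MSD1 (UUG, score 0.792) and ALA1 (ACG, score 0.591).

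Among AUG upstream ORFs the highest rated were in SRD1 (score 0.977), YOL036W (0.965), TRS31 (0.968), PKH2 (0.969) and RAD14 (0.966), scores in the order of the deposited rating. Among near-cognate upstream ORFs they included those in ATP1, the alpha subunit of the mitochondrial ATP synthase (UUG, score 0.941), MSN5 (CUG, score 0.945), EPL1 (UUG, score 0.942) and XRN1, the cytoplasmic exonuclease (AUU, score 0.960). GCN4, the transcription factor under translational control by upstream ORFs, had 18 candidates, of which 7 were rated. Only 3 AUG upstream ORFs of GCN4 were rated. They lie 359, 174 and 149 nucleotides before the annotated AUG and scored 0.943, 0.844 and 0.903. An AUA upstream ORF 429 nucleotides before it scored 0.928, with LTM evidence 17.2 times that of the annotated AUG. AUG upstream ORFs were also rated in HAP4 (score 0.904), CBS1 (score 0.909), FOL1 (score 0.831) and PPR1 (scores 0.671 and 0.532). CLN3, with 5, and YAP1, with 4, had rated upstream ORFs at near-cognate codons alone, DCD1 (AUU, score 0.525) and INO2 (UUG, score 0.839) 1 each, and LEU4 and SCO1 none.

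Gene groups fixed before the data were examined were compared by whether a gene had at least 1 rated upstream ORF. The comparison was with all other genes that had a candidate and an annotated ORF in the table. Of 123 cytosolic ribosomal protein genes, 22 had one (17.9%, against 59.1% of other genes, odds ratio 0.151, adjusted p = 6.26e-19, Fisher's exact test over 13 lists), among them RPL7A, RPS2 and RPP0. Of 53 mitochondrial ribosomal protein genes, 16 had one (30.2%, odds ratio 0.309, adjusted exact p = 3.84e-04). Of 41 genes of mid and late sporulation, 33 had one (80.5%, against 57.7%, odds ratio 3.02, adjusted exact p = 0.0159), including NDT80, CLB3, SPS1 and SSP1. All 3 calls held above 0.8 (adjusted exact p = 2.66e-09, 0.00143 and 0.00747). Above 0.9 the call held for the cytosolic ribosome (adjusted exact p = 0.00276), while the mitochondrial ribosome had 0 of 53 against 6.98% (odds ratio 0.124, adjusted exact p = 0.214) and mid and late sporulation 4 of 41 (odds ratio 1.47, adjusted exact p = 1). The number of candidates per gene was not matched between groups.

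The other 10 lists did not pass the exact test for upstream ORFs. Their shares were 83.3% for genes with known upstream ORFs (10 of 12, adjusted exact p = 0.222), 75% for genes with known alternative starts (6 of 8), 66.7% for the tricarboxylic acid cycle (10 of 15), 65.4% for the proteasome (17 of 26), 62.1% for early meiosis (18 of 29), 56.0% for aminoacyl-tRNA synthetases (14 of 25), 50% for oxidative phosphorylation (15 of 30), 48.1% for translation initiation factors (13 of 27), 36.4% for histones (4 of 11) and 35.3% for glycolysis (6 of 17). At stricter cut-offs 2 of these lists passed, genes with known upstream ORFs above 0.9 (4 of 12, odds ratio 6.83, adjusted exact p = 0.0458) and the tricarboxylic acid cycle above 0.8 (9 of 15, odds ratio 5.16, adjusted exact p = 0.00747). A gene counted through any rated upstream ORF, so 10 of 12 is not a recovery of the known upstream ORFs. At a score above 0.5 CLN3, YAP1, DCD1 and INO2 counted through near-cognate codons alone.

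For near-cognate extensions 0 of 13 lists passed the exact test, with 1 at an unadjusted exact p under 0.05. Of 1523 genes with a candidate and an annotated ORF in the table, 77 had a rated near-cognate extension. Without the second condition there were 1629 genes with a candidate, 93 of them with a rated one. Aminoacyl-tRNA synthetases had 3 of 14 (ALA1, FRS2 and MSY1, 21.4% against 4.90%, unadjusted exact p = 0.0302, adjusted exact p = 0.393). The extensions of FRS2 and MSY1 add 1 codon, with 0.0892 and 0.0542 times the LTM evidence of the annotated AUG. For extensions of that length, the closing part leaves open that reads of the annotated AUG were counted 1 codon upstream. Mid and late sporulation genes had 2 of 13 (CLB1 and MUM2). FOL1, MDH1 and ALA1 were the only members rated among the compared genes, 4 with known upstream ORFs, 8 of the tricarboxylic acid cycle and 6 with known alternative starts. HFA1 and KGD4, whose rated extensions are given above, have no annotated ORF in the table and were not compared. The remaining 8 lists had 0 rated members among 53 genes of the cytosolic ribosome, 22 of the mitochondrial ribosome, 14 of oxidative phosphorylation, 12 initiation factors, 11 early meiotic, 11 proteasome, 7 glycolytic and 5 histone genes. With these numbers of genes, a list of ribosomal proteins with 3 times the odds was found in 35% of simulated draws.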

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

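Both results here were picked because they lie in classes of ORFs that no comparison above uses and exceed the share that a count of 0 would allow; both were chosen after the data had been seen. Any handful of rated ORFs exceeds that share, so it does not separate them from false positives of the score. ORFs that start and end downstream of an annotated gene were rated in 13 of 482 cases (2.70%, exact 95% interval 1.44 to 4.57, against 0.622% allowed by a count of 0), 9 of them with an AUG. The highest score, 0.924, belonged to an AUG ORF of 2 codons downstream of YGR269W at 1044626 of SK1 chromosome 7, and the next, 0.866, to an AUG ORF of 254 codons downstream of ETR1 on chromosome 2. ORFs that run over the stop codon of an annotated gene were rated in 86 of 1093 cases (7.87%, exact 95% interval 6.34 to 9.63, against 0.274%), 57 of them with a near-cognate start. The highest scores were those of CUG ORFs at YER084W (0.867) and CUP1-1 (0.863) and of an AUC ORF at CMI8 (0.854).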

How the results depend on the processing

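The cut-off decided most counts. The cut-offs of 0.1 and 0.8, the minimum of 4 codons, near-cognate and AUG starts alone for extension length and a cut-off of 0.9 for start-overlapping ORFs were added after the data had been seen; the other alternatives were planned. The cause of the changes below was not tested beyond what each alternative leaves in the test.

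At a score above 0.9 there were 3 near-cognate extensions, 1 AUG extension, 362 upstream, 88 start-overlapping, 39 truncated, 219 internal and 70 ORFs on transcripts without a coding sequence, and 47.8% of annotated ORFs. Codons passing were 0 in extensions, 1 in truncations, 0 in internal and 2 in start-overlapping ORFs. The odds ratio of near-cognate starts in extensions against upstream ORFs was 2.03 and of AUG against near-cognate extensions 13.1, both no longer past the threshold. Directions turned in extensions for CUG (2.51), GUG (2.89), AUA (1.77) and AAG (2.44), odds ratios set by empty cells or single ORFs; in truncations for CUG (0.615), GUG (0.784), ACG (2.77), AUC (1.12) and AUA (0.897); in internal ORFs for UUG (1.36), GUG (1.05) and AUA (0.345); and in start-overlapping ORFs for CUG (0.938) and GUG (0.876). Among lists they turned for extensions in aminoacyl-tRNA synthetases (20.8), known alternative starts (46.6), known upstream ORFs (67.4) and the tricarboxylic acid cycle (35.6), all without a rated gene, so that the odds ratio comes from the 0.5 added to each cell. For upstream ORFs they turned in aminoacyl-tRNA synthetases (1.18), known alternative starts (0.791), the tricarboxylic acid cycle (0.964), oxidative phosphorylation (2.09) and the proteasome (0.253).

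At a score above 0.8 there were 22 near-cognate and 12 AUG extensions, 1544 upstream, 330 start-overlapping, 242 truncated, 1162 internal and 294 ORFs without a coding sequence, and 79.3% of annotated ORFs. Codons passing were 0 in extensions, 1 in truncations, 2 in internal and 3 in start-overlapping ORFs, and the odds ratio of extensions against upstream ORFs was 1.08. Directions turned in extensions for GUG (0.446), ACG (1.26) and AUU (1.57), in upstream ORFs for GUG (0.989), in truncations for CUG (0.497), GUG (0.31), ACG (1.1) and AUC (1.25), and in internal ORFs for UUG (1.33). Lists turned for extensions in known alternative starts (7.98), known upstream ORFs (11.5) and the tricarboxylic acid cycle (6.09), again from empty cells, and for upstream ORFs in aminoacyl-tRNA synthetases (1.61) and early meiosis (0.889).

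At a score above 0.1 there were 596 near-cognate extensions, 30642 upstream, 5457 start-overlapping, 6553 truncated, 94843 internal and 8816 ORFs without a coding sequence, and 99.3% of annotated ORFs, so that most classes were close to saturated. Codons passing were 5 in extensions, 3 in upstream, 8 in truncated, 5 in internal and 3 in start-overlapping ORFs. The difference in extension length was 0, and 0 lists passed for upstream ORFs, a test without content because all 4350 genes then had a rated upstream ORF. Directions turned in extensions for ACG (1.32), in upstream ORFs for AUA (1.11), in truncations for ACG (1.36), in internal ORFs for CUG (0.913), ACG (0.881), AUU (1.29) and AGG (1.08), in start-overlapping ORFs for ACG (1.09), AUU (1.03) and AUA (1.06), and for extensions in the lists glycolysis (1.05) and mid and late sporulation (0.473).

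For AUG starts alone the difference in extension length turned to -8 codons (permutation p = 0.163), against 9.5 for near-cognate starts alone. With each gene counted by its best ORF there were 2770 upstream, 3468 internal and 214 ORFs without a coding sequence. Codons passing were 4 in extensions and 5 in internal ORFs. AUU in extensions (1.12), GUG in truncations (0.914) and UUG in internal ORFs (1.15) turned. With at least 20 codons there were 1376 upstream, 690 start-overlapping, 2207 internal and 453 ORFs without a coding sequence. AUU in extensions also turned at a minimum of 10 (1.11) and of 4 codons (1.17), and ACG in upstream ORFs of at least 10 codons (1.08). In genes whose annotated ORF was rated, ACG in extensions (1.07) and in upstream ORFs (1.05), and the lists known upstream ORFs for extensions (2.66) and aminoacyl-tRNA synthetases for upstream ORFs (1.13), turned.

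UUG above and AAG below the other codons in upstream ORFs kept their direction under every alternative run, and 7 codons passed under each except a score above 0.1. The higher odds of AUG in upstream ORFs passed under all alternatives, at 1.60 to 5.39. Of the values for single codons, lists and further classes, all codons of upstream ORFs included, 209 kept direction and side, 45 lost and 13 gained the threshold, and 59 turned, as given above. Among those that gained were the upstream ORF lists known upstream ORFs above 0.9 (6.83) and the tricarboxylic acid cycle above 0.8 (5.16), and among those that lost were the 3 lists of the saturated test above 0.1. No paired analysis was possible because each group has a single library and the table has no columns for libraries. The planned scaling and filter alternatives for conditions were not run for the same reason.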

Other observations

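ORFs on transcripts that carry no annotated coding sequence in the table formed a class of their own, with 1342 of 10541 candidates rated. The highest by the deposited rating, given with forest scores, were an AAG ORF of 14 codons at FLO11, the flocculin gene (score 0.971), AUG ORFs of 429 codons at ECM33, a cell wall protein (0.917), 379 codons at FRA1 (0.929), 31 codons at SPO22, a meiosis-specific gene (0.960), and 3 codons at YER186C (0.954). Those at ECM33, FRA1 and SPO22 begin at the gene's own annotated start. UUG again exceeded AAG in start-overlapping ORFs, and the ranks of the 9 codons in upstream ORFs correlated with those in start-overlapping ORFs (Spearman's rho 0.983), extensions (0.833), truncations (0.783) and ORFs of this class (0.717), but little with those inside coding regions (0.117); codons are not independent replicates.

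The tests of distance from the annotated start, of UUG inside coding regions, of G content, of the mitochondrial term and of annotated starts on transcripts without a coding sequence were chosen after the result, or the gene names behind it, had been seen. The other tests in this part were written before.

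The first pattern is the high share of near-cognate extensions 1 codon upstream of the annotated AUG, 6.16% against 1.06% at 2 to 9 codons (odds ratio 6.16, 95% interval 3.03 to 12.5, p = 1.05e-06, Fisher's exact test). Reads of the annotated AUG counted 1 codon upstream are a candidate explanation. If so, UUG, CUG and GUG should have no advantage at 1 codon, where their odds ratio against the other 6 codons was 1.51 (95% interval 0.415 to 5.51), while at 10 or more codons it was 2.54 (1.53 to 4.22). All 5 rated AGG extensions and 4 of 5 rated AAG extensions were 1 codon long. Of the candidates, 98 of 148 AGG and 264 of 454 AAG extensions added at least 4 codons. How many AGG and AAG candidates were 1 codon long is not given, so this excess has no measured size. The ratio of both odds ratios, 0.595 (0.148 to 2.39), leaves the explanation open. No biological explanation was tested.

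The second pattern is the order of codons in upstream ORFs. AUG codons close by could lend reads to near-cognate neighbours, and 1407 near-cognate ORFs have an AUG candidate within 6 nucleotides. Without these ORFs the odds ratio of UUG was 2.70 (95% interval 2.51 to 2.90), against 2.65 with them. The share of AAG was 3.64% without and 4.07% with them. AUG candidates within that distance therefore did not raise UUG above the other codons. A codon preference of library preparation that acts anywhere in a transcript would raise UUG inside coding regions too. There its odds ratio was 0.911 (0.836 to 0.994) in out-of-frame ORFs, but 2.13 (1.69 to 2.69) in truncations, and above a score of 0.8 it was 1.33 (adjusted exact p = 0.183) and 3.56, against 3.62 in upstream ORFs. As both classes inside coding regions disagree, such a preference stays open. Preferences limited to regions before coding sequences, and the score's different baseline by class, remain open, and no biological explanation was tested by the design.

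The third pattern is the frequent rating of AUG extensions. An SK1 annotation that starts later than the S288C annotation is a possible explanation, but 0% of the 28 rated AUG extensions had the length of the S288C protein (upper 95% limit 12.3%), and in 26 of 28 the annotated SK1 protein had exactly that length. Whether the annotation of both strains starts late in these genes was not tested.

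A hypothesis is that sequence context helps a near-cognate codon to start translation, as an A at position -3 (3 bases before the start codon) does for AUG. In 3569 rated and 13401 unrated near-cognate upstream ORFs found in S288C, A stood at -3 in 44.6% and 35.4%, an odds ratio of 1.53 within codons (95% interval 1.42 to 1.65, permutation p = 2e-05, the smallest that the two-sided test can give). At the other positions from -12 to -1 the odds ratio of A lay between 0.929 and 1.15, and that of A at +4 was 1.24 (1.14 to 1.34). Bases differed along the whole stretch, since G was rarer in rated ORFs, with its whole interval below 1, at 10 of the 12 positions (0.705 to 0.857). A low G content of the stretch is a possible explanation for position -3 too, but within strata of start codon and number of G at the other positions the odds ratio of A at -3 was 1.58 (1.46 to 1.70), which argues against it as the whole cause. T at -3 was rarer as well (0.634). In extensions, 86 rated against 2352 unrated, the odds ratio of A at -3 was 1.72 (1.11 to 2.68, permutation p = 0.022), but there C at -5 (1.73, 1.05 to 2.87) and C at -4 (1.71, 1.03 to 2.85) had odds ratios as large, so A at -3 did not stand out in extensions. In simulated tables of 16970 upstream ORFs a true odds ratio of 1.5 gave a median estimate of 1.51, and 1% of tables without an effect had an interval above 1. For upstream ORFs the result at -3 is consistent with a role of context, beside a difference in composition whose cause was not tested, in S288C sequence and not in that of SK1.

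A hypothesis that near-cognate extensions, like that of ALA1, may often serve import into mitochondria found no support in the genes compared. These had a candidate and an annotated ORF in the table, which held for 77 of the 93 genes with a rated near-cognate extension. HFA1 and KGD4, named above for mitochondrial proteins, were not among them, so the test does not cover these genes. Genes with the mitochondrion term in the deposited annotation had a rated near-cognate extension in 13 of 274 cases (4.74%) and other genes in 64 of 1249 (5.12%), an odds ratio of 0.922 (95% interval 0.501 to 1.70, p = 0.88, Fisher's exact test), which leaves both a lower and a moderately higher rate possible. For extensions of at least 4 codons the odds ratio was 0.537 (0.228 to 1.27, exact p = 0.212), with 6 genes with the term and 50 others rated, and above a score of 0.1 it was 0.780 (0.575 to 1.06, exact p = 0.117). Peptides added by rated extensions of at least 10 codons were not more positively charged either, as charge was counted here. Their net charge per residue was 0.0929 ± 0.0854 (SD over 55 extensions), against 0.111 ± 0.127 in 825 unrated ones, a difference of -0.0177 (permutation p = 0.306). The start codon was counted by its own amino acid, so each AAG or AGG start added a positive charge. At 10 or more codons, 1 of 127 AAG and 0 of 42 AGG candidates were rated, so this raised mainly the unrated mean. The test therefore does not decide whether the added peptides differ in charge.

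Rated AUG ORFs on transcripts without an annotated coding sequence may in part start at the annotated AUG of known genes. Of 204 genes with such an ORF, 120 (58.8%, exact 95% interval 51.7 to 65.6) had one that begins at the gene's own annotated start. The annotated coding length was not a multiple of 3 in any of the 221 genes of this class, rated or not. Over the deposited annotation such a length was found in 586 of 6707 genes. The class thus held only genes with a broken annotated frame. Of the 120 ORFs at the annotated start, 99 were shorter than the S288C protein of the gene. A rated AUG ORF with the length of the S288C protein was found in 10 of the 204 genes. Many ORFs of this class therefore lie in known genes and are not ORFs outside genes. Whether the broken frame accounts for their ratings was not tested.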
